A study of Mus musculus with 4 samples.

How the data were processed

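RNA from lung tissue of wild-type C57BL/6 mice, treated with bleomycin or PBS for 10 days, was sequenced, and 4 libraries, 2 per group, were used. Groups and replicate numbers come from the sample titles. The authors deposited 1 table of FPKM values per gene with 2 decimals, per the file headers and the labels. Bowtie2 and HISAT and the builds mm10 and GRCm38 are named in the submitters' processing notes. The role of each aligner, the quantification tool and the versions are not given in the sources used here. FPKM scales each library to its own total of fragments, so a gene that takes a large share of fragments lowers the others. Scgb1a1 took 11.2% and 8.35% of summed FPKM with PBS and 3.98% and 4.28% with bleomycin. These are not shares of fragments, since FPKM also divides by transcript length.

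The table held 17692 rows. A row without a gene name, at most 0.0009% of any library's sum, was left out, and 27 names turned into dates by a spreadsheet were restored through their RefSeq transcript accessions, leaving 17691 genes. Of these, 1 had a dash for a name and was kept under its transcript. Of the symbols, 16961 matched the reference gene table, assembly GRCm38.p6, from which chromosomes and positions come. All transcripts are of the curated mRNA kind, and mitochondrially encoded genes numbered 0. Because the unit is FPKM, depth was estimated from low values of genes with 1 transcript of 300 to 1000 bases, between 0.03 and 0.3 FPKM, as the step that 1 fragment makes. At the estimate, 80.5% to 86.7% of values lay within 0.15 of a whole fragment, against 30% by chance at a fixed depth. The depth was picked as the best for these same values, so the comparison overstates the fit. The estimate uses annotated rather than effective transcript length. Squared differences between replicates had medians of 3.2 times the sampling noise for the PBS pair and 9.14 times for the bleomycin pair, so neither pair was counted as 1 library. Pearson correlations of log2 values were 0.997 for the PBS pair, 0.988 for the bleomycin pair and 0.967 to 0.974 across groups.

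Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on 12986 genes with a mean of at least 1 FPKM over the 4 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior degrees of freedom were 2.76 and the residual ones 2. Fold changes are on the log2(value + pseudocount) scale, which understates the change of low genes. Gene lists, 56 in all and 17 of them metabolic, were fixed before the data were examined, and 859 of 863 members asked for are in the table. The 53 lists with at least 3 tested genes were tested with camera (preset correlation 0.01, variance trend), with camera with an estimated correlation and with fry, adjusted over the lists. With an estimated correlation camera rests on the residual degrees of freedom, 2 here, and so has little power to call a list. Counts adjusted over the list alone use the p-values of that list's genes.

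Named genes follow a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among called genes without overlap between groups, leaving out predicted genes, immune receptor segments, Xist and Y-linked genes; up to 4 called members per list with the largest change, or, where fewer than 2 passed, up to 2 with the highest mean as values; and a fixed panel of genes of fibrosis and metabolism. Sex-linked genes, some clock genes and hepatocyte genes other than those among the 10 largest falls lie outside it and were chosen after their values were seen. Some genes that the rule takes are not reported here.

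The functions were tested on simulated data for the bleomycin and PBS comparison, with 12986 genes of which 200 were changed. Errors were drawn independently for each gene from the variance that limma gave it, scaled by a factor per group shared by all genes. Genes that vary widely with bleomycin alone are therefore not represented. With the groups' ratio of median spreads as measured, 81% of 100 genes changed 2-fold and 96% of 100 changed 4-fold were called. There were 15 false calls among 192. With equal spread the shares were 79% and 100%, with 17 false calls among 196. Alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, quantile normalization, rescaling to TPM, upper quartile scaling, eBayes without trend and robust, a replicate block, and leaving out each library. Added after seeing the data were fits without sex chromosome genes, without hepatocyte, haemoglobin, platelet and clock genes, and with array weights by group. Counts were not used here, so no count model was run. Tables were prepared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.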

Results

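Lung tissue of wild-type C57BL/6 mice aged 6 to 8 weeks was compared by RNA sequencing. The mice had been given bleomycin, a DNA-breaking drug used to provoke lung injury and fibrosis, or PBS, a buffer, by the nose, with a treatment time of 10 days. The files hold 4 libraries, 2 per group, with deposited FPKM values (fragments scaled to transcript length and library total) for 17691 genes. The labels' protocol speaks of 4 groups of mice and the design text of 3 replicates, while 2 groups of 2 libraries were analysed here. From the steps that single fragments leave in low values, the depth was estimated at 17100000 and 17200000 fragments for the PBS libraries and 17000000 and 17500000 for the bleomycin libraries. Genes above 0 numbered 16536 and 16458 with PBS and 16901 and 16618 with bleomycin. The labels do not state that the libraries came from separate animals. The limma p-values therefore measure only the spread between these samples, which may be technical. Camera with a preset correlation sets the genes of a list against the other genes and counts them as nearly independent. Its p-values can thus be very small with 2 libraries per group and do not measure the spread between animals.

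The comparison asks which genes, in particular those of metabolism that the series title points to, differed in lung after bleomycin. On the log2(FPKM + 1) scale the largest rise was that of Eln, the gene of elastin (gene 13717, GRCm38.p6 chromosome 5, 134702595 to 134747368). Eln went from 116 ± 17.4 to 3117 ± 2649 FPKM (SD, n = 2 per group, as for all values here). This is a log2 fold change of 4.43 ± 0.67 (SE, adjusted p = 0.0202 by limma). Tnc, which encodes the matrix protein tenascin C (chromosome 4, 63959785 to 64047015), rose from 2.21 ± 0.255 to 42.1 ± 8.53 FPKM. Cldn4, which encodes a tight junction claudin (chromosome 5, 134945123 to 134946934), rose from 2.1 ± 0.0636 to 34.6 ± 2.26 FPKM. Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874737), rose from 11.2 ± 0.785 to 119 ± 12.1 FPKM. Spp1, the gene of osteopontin (chromosome 5, 104435111 to 104441053), rose from 53.8 ± 5.38 to 649 ± 291 FPKM. Among the largest falls, Inmt, a methyltransferase gene marking lung fibroblasts (chromosome 6, 55170627 to 55174990), went from 2632 ± 429.6 to 241 ± 103 FPKM. Cyp1a1, a xenobiotic-metabolizing cytochrome P450 (chromosome 9, 57687928 to 57703824), fell from 30.3 ± 5.69 to 2.18 ± 1.56 FPKM.

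The other genes among the 10 largest rises were Saa3, Mmp12, Retnla, Sprr1a and Trem2, with log2 fold changes of 3.82 ± 0.81, 3.79 ± 0.79, 3.47 ± 0.17, 3.11 ± 0.18 and 3.05 ± 0.21. Eln, Saa3 and Mmp12 differed widely between the bleomycin libraries, with 1243 and 4990 FPKM for Eln, 417 and 72.9 FPKM for Saa3 and 78.3 and 13.9 FPKM for Mmp12. The other 8 of the 10 largest falls were Saa2 (-3.62 ± 0.14), Saa1 (-3.30 ± 0.14), Colq (-3.28 ± 0.22), Fabp1 (-3.23 ± 0.53), Hamp (-3.14 ± 0.15), Slc7a10 (-3.11 ± 0.59), Alb (-3.07 ± 0.14) and Mup10 (-3.01 ± 0.10). Saa1, Saa2, Hamp, Alb, Mup10 and Fabp1 are abundant in liver, and their levels are taken up with other hepatocyte transcripts further on. Saa1 and Saa2, the Mup genes and the haemoglobin genes are near-identical families whose fragments the authors' counting could split between members, so values of single members are uncertain.

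In all, 1116 of 12986 genes rose, 998 fell and 10872 did not pass limma at an adjusted p under 0.05, and 393 of the rises and 315 of the falls reached a log2 change of 1. All 2114 called genes separated the groups without overlap, as did 66.5% of the tested genes, against 33.3% by chance. The bleomycin libraries lay farther apart than the PBS libraries, with median SDs of 0.115 and 0.0637 on the log2 scale. The groups also differed in sex-linked transcripts, Eif2s3y, a Y-linked gene chosen after its values were seen, being at 26.4 and 28.9 FPKM with PBS and listed at 0 in both bleomycin libraries. Leaving out a PBS library leaves the spread to the bleomycin pair, and limma then called 0 genes. It gave 1137 higher and 993 lower at an unadjusted p under 0.05 without PBS replicate 1 and 1160 and 1048 without PBS replicate 2. Leaving out a bleomycin library gave 2318 rises and 3180 falls without replicate 1 and 2393 and 1992 without replicate 2.

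**Figure D1:**
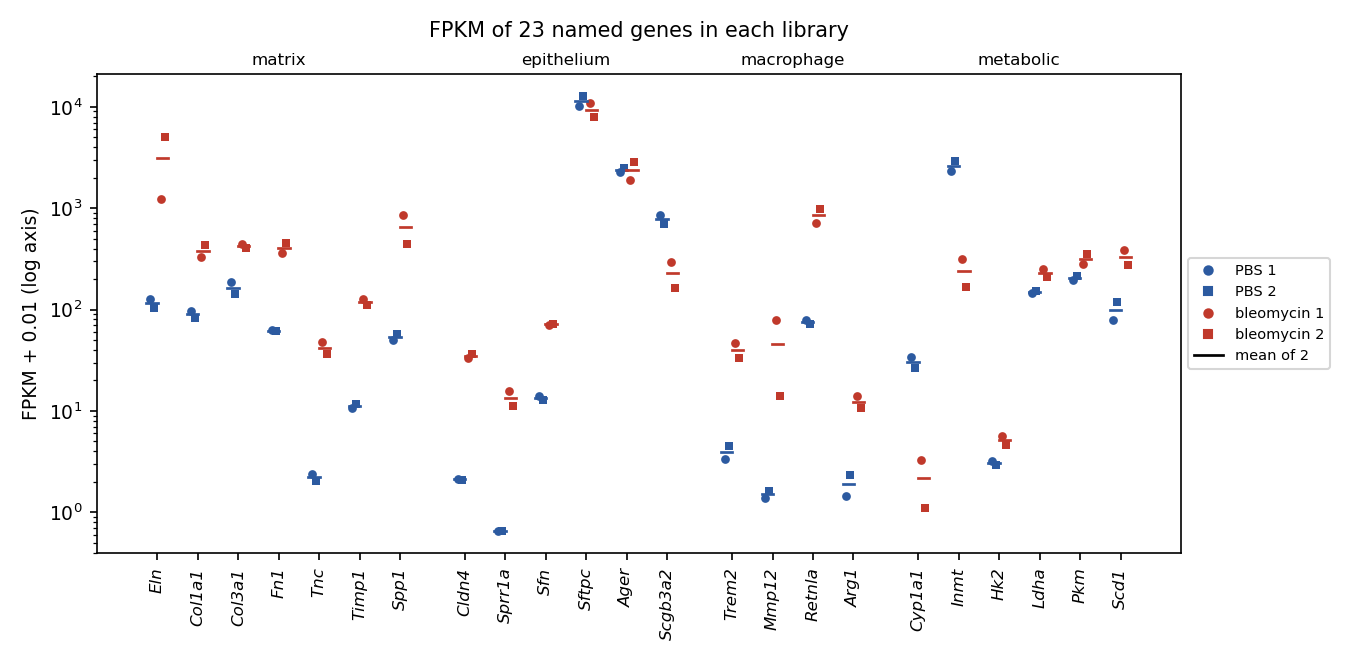
FPKM (with 0.01 added, log axis) of 23 named genes in the 2 PBS and 2 bleomycin libraries, each symbol a library and each bar the mean of 2. Eln spans 103 to 128 FPKM with PBS and 1243 to 4990 FPKM with bleomycin, while Sftpc and Ager overlap between the groups.

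Metabolic genes moved in both directions after bleomycin. Xenobiotic metabolism genes fell most. Cyp1a1 fell 13.9-fold and the glutathione transferase gene Gsta3 went from 193 ± 14.7 to 31 ± 3.51 FPKM. Cyp2f2 fell from 1078 ± 342 to 261 ± 97.9 FPKM and Cyp4b1 from 407 ± 30.8 to 104 ± 6.78 FPKM. Of 21 genes on that list 0 rose, 14 fell and 7 did not pass (0 higher and 18 lower adjusted over the list alone), and the list was lower as a whole (camera adjusted p = 2.23e-09, adjusted p = 0.349 with an estimated correlation). The club and secretory cell list was lower in the same libraries (camera adjusted p = 0.0226, adjusted p = 0.58 with an estimated correlation). Hepatocyte transcripts were lower there too, with Alb falling from 14.3 ± 0.141 to 0.835 ± 0.247 FPKM. With PBS, Alb stood far below Cyp2f2, Cyp4b1 and Gsta3, and whether liver RNA has any part in the falls of the xenobiotic list was not tested. Some glycolysis genes rose, with Eno1 (enolase) from 104 ± 2.03 to 193 ± 25.3 FPKM and Gapdh from 486 ± 8.51 to 847 ± 62.3 FPKM. Pgam1 rose from 63.7 ± 0.0566 to 106 ± 1.58 FPKM, Aldoc from 2.12 ± 0.247 to 4.13 ± 0.212 FPKM and Ldha, which makes lactate, from 149.7 ± 3.97 to 231 ± 30.6 FPKM. Of 20 glycolysis genes 8 rose, 1 fell and 11 did not pass (10 higher and 1 lower adjusted over the list alone). The glycolysis list was higher (camera adjusted p = 0.00151, adjusted p = 0.486 with an estimated correlation). Hk2 and Pkm did not pass (adjusted p = 0.0547 and adjusted p = 0.0534 by limma). Hk2 was at 3.07 ± 0.226 FPKM with PBS and 5.11 ± 0.785 FPKM with bleomycin, and Pkm at 205 ± 13 FPKM with PBS and 318 ± 53.3 FPKM with bleomycin. Over the union of the 17 metabolic lists, 42 of 299 tested genes rose, 30 fell and 227 did not pass, or 59 higher and 39 lower adjusted over the list alone. Without a PBS library limma called 0 of these genes, and without bleomycin replicate 1 it called 102 higher and 67 lower, without bleomycin replicate 2 98 and 56.

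Some genes of lipid uptake rose. Msr1, a macrophage scavenger receptor, went from 0.955 ± 0.106 to 10.4 ± 1.7 FPKM and Lpl (lipoprotein lipase) from 40.8 ± 4.35 to 99.4 ± 4.29 FPKM. Npc2 rose from 215 ± 21.1 to 401 ± 30.8 FPKM and Lipa (lysosomal lipase) from 34.8 ± 0.375 to 61 ± 2.88 FPKM. Of 16 lipid uptake and efflux genes 4 rose, 0 fell and 12 did not pass (8 higher and 1 lower adjusted over the list alone). The lipid uptake and efflux list was higher (camera adjusted p = 0.00431, adjusted p = 0.589 with an estimated correlation). The recruited macrophage list was higher in the same libraries, with a median of 1.33 and 11 of 16 genes risen (camera adjusted p = 1.64e-06, adjusted p = 0.58 with an estimated correlation). Pparg, of the lipid uptake list, was at 5.73 ± 0.17 FPKM with PBS and 5.49 ± 0.601 FPKM with bleomycin. Cholesterol synthesis was higher as a list (camera adjusted p = 0.00288, adjusted p = 0.615 with an estimated correlation), although of 22 genes 2 rose, 0 fell and 20 did not pass (2 higher and 0 lower adjusted over the list alone). Among them, Mvd rose from 7.6 ± 1.41 to 17.1 ± 3.72 FPKM. In fatty acid synthesis, Scd1, the stearoyl-CoA desaturase, rose from 98.3 ± 28.4 to 332 ± 80.6 FPKM. Me1 rose from 17.9 ± 1.36 to 29.9 ± 2.31 FPKM and Slc25a1 from 25.8 ± 0.0495 to 35.8 ± 1.26 FPKM, while Acss2 fell from 10.8 ± 0.163 to 5.45 ± 0.0849 FPKM. Of 16 genes there 3 rose, 1 fell and 12 did not pass (5 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.796). Fasn was at 25.9 ± 3 FPKM with PBS and 33.7 ± 0.566 FPKM with bleomycin. Glycerolipid and phospholipid synthesis held 4 falls and no rise among 16 genes, with 5 lower and 0 higher adjusted over the list alone. They were Lpin1 (-1.11 ± 0.15), Chpt1 (-0.76 ± 0.09), Lpin2 (-0.62 ± 0.08) and Chka (-0.38 ± 0.08), and the list did not pass by camera (camera adjusted p = 0.156) but was lower by fry (adjusted p = 0.0337).

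Mitochondrial lists held few called genes. In the respiratory chain Cox5a rose from 72.8 ± 2.88 to 105 ± 0.0283 FPKM. Of 34 genes 1 rose, 0 fell and 33 did not pass (1 higher and 0 lower adjusted over the list alone). With a median log2 change of 0.15 the list was higher by camera (camera adjusted p = 0.00488, adjusted p = 0.649 with an estimated correlation). The PBS libraries differed by a median of 0.14 over the same genes, about as much, and fry gave an adjusted p of 0.263. None of 23 genes of pyruvate entry and the TCA cycle passed (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.796). Mdh2 was at 88.9 ± 4.47 FPKM with PBS and 108 ± 0.735 FPKM with bleomycin and Sdhc at 76.2 ± 4.21 FPKM with PBS and 86.8 ± 0.679 FPKM with bleomycin. In fatty acid oxidation Acads rose from 8.13 ± 0.544 to 11.3 ± 0.099 FPKM and Acaa2 fell from 67.8 ± 1.89 to 46.7 ± 3.46 FPKM. Of 20 genes 1 rose, 1 fell and 18 did not pass (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.849). Cpt1a, which admits fatty acids to mitochondria, was at 31 ± 0.431 FPKM with PBS and 29.3 ± 7.81 FPKM with bleomycin, and Ppargc1a lay below the filter at 0.64 and 0.43 FPKM with PBS and 0.39 and 0.38 FPKM with bleomycin. The regulators Myc and Hif1a rose from 4.11 ± 0.12 to 11.5 ± 0.94 FPKM and from 15.3 ± 0.262 to 27.3 ± 4.09 FPKM.

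Amino acid and nucleotide genes rose in part. P4ha3, a collagen prolyl hydroxylase subunit, went from 0.81 ± 0.113 to 13.8 ± 7.4 FPKM and Arg1 (arginase) from 1.9 ± 0.629 to 12.3 ± 2.4 FPKM. Nos2 rose from 1.4 ± 0.0212 to 4.69 ± 0.509 FPKM and the proline synthesis enzyme gene Aldh18a1 from 3.25 ± 0.318 to 8.74 ± 0.368 FPKM. Of 15 arginine, proline and polyamine genes 5 rose, 1 fell and 9 did not pass (7 higher and 2 lower adjusted over the list alone). The arginine, proline and polyamine list was higher (camera adjusted p = 0.0205, adjusted p = 0.58 with an estimated correlation). Nucleotide synthesis was higher (camera adjusted p = 0.00431, adjusted p = 0.58 with an estimated correlation). Of 19 genes 4 rose, 1 fell and 14 did not pass (7 higher and 1 lower adjusted over the list alone). Tk1 rose by 1.73 ± 0.09, Rrm2 by 1.56 ± 0.13, Ctps by 1.48 ± 0.08 and Rrm1 by 0.93 ± 0.10 on the log2 scale. Among 17 genes of glutamine, serine and folate-carbon metabolism 4 rose, 2 fell and 11 did not pass (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0808). By fry that list was higher (adjusted p = 0.0403). Mthfd2 (1.45 ± 0.14), Psat1 (1.28 ± 0.13) and the amino acid transporter gene Slc7a5 (1.06 ± 0.14) rose, and Glul, the glutamine synthetase gene, fell from 240.3 ± 12.2 to 119 ± 24.8 FPKM.

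The remaining metabolic lists did not pass by camera. In the pentose phosphate pathway Pgd rose (0.73 ± 0.09). Of 7 genes 1 rose, 0 fell and 6 did not pass (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0568), with Taldo1 and Tkt at log2 changes of 0.28 ± 0.11 and 0.16 ± 0.10. Kynu (0.95 ± 0.19) and Nnmt (0.85 ± 0.08) rose in tryptophan and NAD metabolism. Of 10 genes 2 rose, 0 fell and 8 did not pass (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.86). Hpgd, which degrades prostaglandins, fell from 370.2 ± 50.1 to 149 ± 19.1 FPKM, while Ptges (0.93 ± 0.10), Hpgds (0.82 ± 0.14) and Alox5ap (0.57 ± 0.12) rose. Of 12 eicosanoid genes 3 rose, 2 fell and 7 did not pass (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0568). Sod1 and Cat, which remove superoxide and peroxide, fell from 697 ± 9.17 to 355 ± 5.98 FPKM and from 82.8 ± 6.27 to 44.1 ± 6.48 FPKM, while Txnrd1 (0.64 ± 0.10) and Prdx1 (0.57 ± 0.10) rose. Of 19 glutathione and antioxidant genes 3 rose, 2 fell and 14 did not pass (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.813). Hyal1 fell (-0.78 ± 0.12) and Gnpnat1 rose (0.48 ± 0.09) among 12 hexosamine and glycosaminoglycan genes, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.119). By fry this list was higher (adjusted p = 0.0403).

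**Figure D2:**
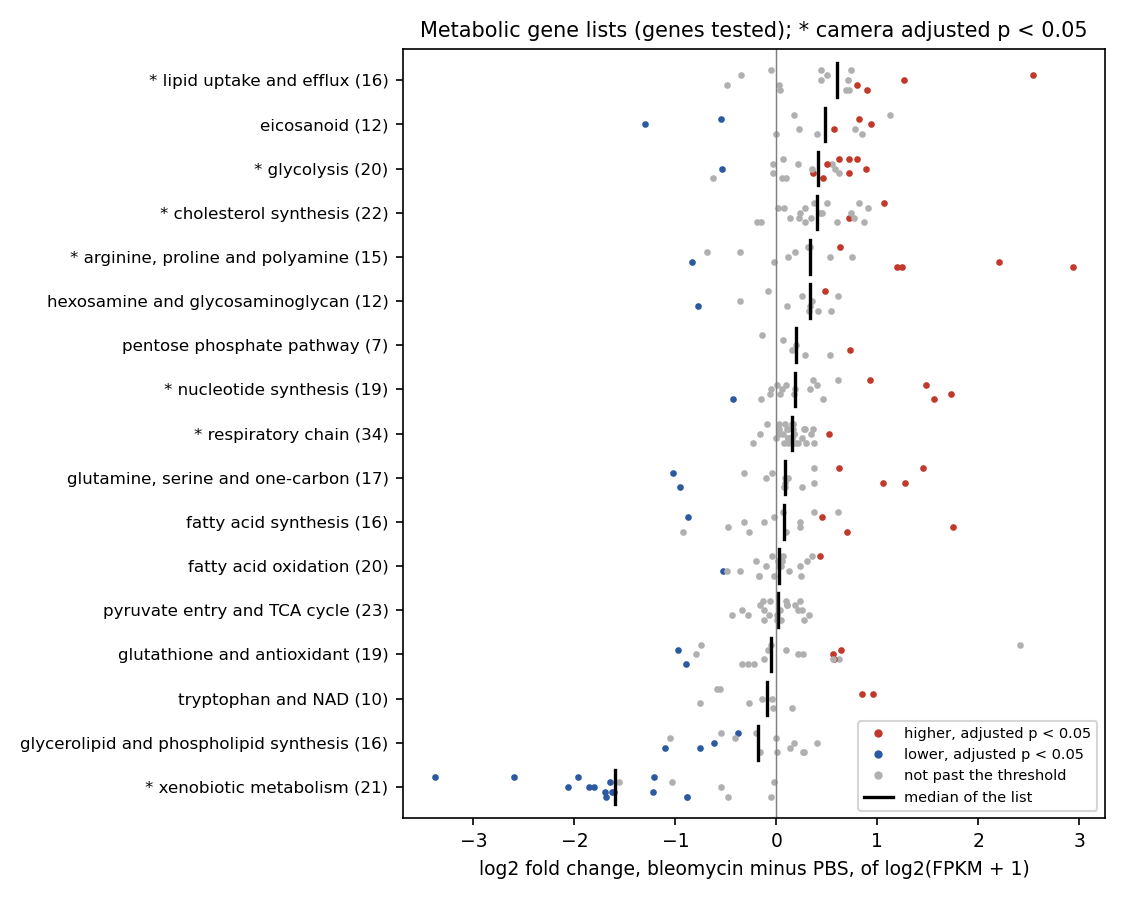
Log2 fold change (bleomycin minus PBS, on log2(FPKM + 1)) of each tested gene of the 17 metabolic lists, one point per gene, coloured by its limma call, with the list median as a black bar and the number tested in brackets. Xenobiotic metabolism has a median of -1.60 and lipid uptake and efflux one of 0.60.

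Most interstitial matrix genes rose. Besides Eln and Tnc, Fn1 (fibronectin) went from 62 ± 0.396 to 409 ± 69.2 FPKM and Col5a2 from 20.1 ± 2.96 to 96.7 ± 38.5 FPKM. Col1a1 rose from 89.9 ± 9.5 to 381 ± 75.9 FPKM and Col3a1 from 164 ± 29.8 to 422 ± 26.6 FPKM. Of 25 interstitial matrix genes 17 rose, 1 fell and 7 did not pass (21 higher and 1 lower adjusted over the list alone). The interstitial matrix list was higher (camera adjusted p = 2.23e-09, adjusted p = 0.58 with an estimated correlation). Ctsk (cathepsin K) rose from 16.5 ± 0.339 to 98.7 ± 33.3 FPKM and the membrane metalloproteinase gene Mmp14 from 21.4 ± 1.91 to 105 ± 23.1 FPKM. Of 21 remodelling genes 11 rose, 1 fell and 9 did not pass (15 higher and 1 lower adjusted over the list alone). The matrix remodelling list was higher (camera adjusted p = 8.53e-07, adjusted p = 0.349 with an estimated correlation). Thbs1 rose from 25.1 ± 3.19 to 164 ± 0.898 FPKM and Ltbp2 from 18.7 ± 2.17 to 109 ± 50.1 FPKM. Ctgf rose from 121 ± 3.73 to 422 ± 210.1 FPKM and Acta2, the smooth muscle actin of myofibroblasts, from 44.6 ± 0.976 to 134 ± 48.8 FPKM. The myofibroblast and TGF-beta list was higher (camera adjusted p = 1.91e-06, adjusted p = 0.349 with an estimated correlation). Of 13 genes 9 rose, 0 fell and 4 did not pass (11 higher and 0 lower adjusted over the list alone). In the basement membrane list Col4a1 (1.49 ± 0.18), Col4a2 (1.13 ± 0.20) and Hspg2 (0.68 ± 0.10) rose. Of 15 genes 6 rose, 0 fell and 9 did not pass (8 higher and 1 lower adjusted over the list alone). The basement membrane list was higher (camera adjusted p = 0.00151, adjusted p = 0.649 with an estimated correlation).

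Most cell cycle and p53 target genes rose. Ccna2 went from 2.27 ± 0.424 to 12.4 ± 1.37 FPKM and Prc1 from 2.51 ± 0.368 to 12.7 ± 1.21 FPKM. Ccnb1 rose from 1.11 ± 0.148 to 7.04 ± 0.17 FPKM and Cdk1 from 1.27 ± 0.184 to 7.26 ± 0.849 FPKM. Of 29 cell cycle genes 23 rose, 0 fell and 6 did not pass (27 higher and 0 lower adjusted over the list alone). The cell cycle list was higher (camera adjusted p = 2.44e-16, adjusted p = 0.58 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose from 49.6 ± 0.898 to 254 ± 26.8 FPKM and Gdf15 from 0.945 ± 0.361 to 8.24 ± 1.85 FPKM. Ccng1 rose from 28.6 ± 0.728 to 75.9 ± 5.6 FPKM and Eda2r from 0.87 ± 0.283 to 3.46 ± 0.502 FPKM. Of 17 genes of the p53 response 11 rose, 0 fell and 6 did not pass (11 higher and 0 lower adjusted over the list alone). The p53 response and senescence list was higher (camera adjusted p = 6.6e-06, adjusted p = 0.349 with an estimated correlation).

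Epithelial lists parted. Transitional alveolar epithelium, a state described between type II and type I cells, was higher (camera adjusted p = 4.71e-09, adjusted p = 0.349 with an estimated correlation). Of 11 genes 9 rose, 0 fell and 2 did not pass (10 higher and 0 lower adjusted over the list alone). Besides Cldn4, Sfn rose from 13.4 ± 0.75 to 71.3 ± 1.12 FPKM. Itgb6 rose from 4.75 ± 0.948 to 26.7 ± 6.22 FPKM and Lcn2 from 109 ± 15.6 to 464 ± 96.1 FPKM. Of 13 type II genes 3 rose, 0 fell and 10 did not pass (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.157). Napsa (0.86 ± 0.16), Sftpd (0.81 ± 0.11) and Muc1 (0.59 ± 0.11) rose. Sftpc was at 11505 ± 1816 FPKM with PBS and 9398 ± 2099 FPKM with bleomycin. Of 13 type I genes 2 rose, 3 fell and 8 did not pass (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.953). Igfbp2 (1.16 ± 0.14) and Pdpn (0.65 ± 0.12) rose there, Cav1 (-0.89 ± 0.10) and Rtkn2 (-0.80 ± 0.09) fell, and Ager was at 2369.8 ± 142 FPKM with PBS and 2358 ± 672 FPKM with bleomycin. Club and secretory genes were lower (camera adjusted p = 0.0226, adjusted p = 0.58 with an estimated correlation). Pon1 fell from 30.7 ± 7.08 to 5.96 ± 0.601 FPKM and Scgb3a2 from 778 ± 118 to 230.3 ± 94.1 FPKM. Cldn10 fell from 21 ± 3.92 to 7.83 ± 1.42 FPKM and Cckar from 20 ± 5.91 to 8.47 ± 1.86 FPKM. Of 8 genes 0 rose, 4 fell and 4 did not pass (0 higher and 4 lower adjusted over the list alone). Ciliated cell genes were lower as a list (camera adjusted p = 0.000687, adjusted p = 0.645 with an estimated correlation). Tppp3 fell from 401 ± 8.8 to 106 ± 64.2 FPKM. Of 14 genes 0 rose, 1 fell and 13 did not pass (0 higher and 0 lower adjusted over the list alone). Foxj1 and Dynlrb2, also of that list, had log2 changes of -0.72 ± 0.29 and -0.99 ± 0.35 without passing. A single basal cell gene was tested, Krt14 at 0.265 ± 0.0495 FPKM with PBS and 2.15 ± 1.67 FPKM with bleomycin. It did not pass over all genes (adjusted p = 0.104 by limma). Over the list alone it counts as 1 higher, but with 1 gene nothing is adjusted, and its unadjusted p was 0.030 by limma.

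Part of the endothelial and resident fibroblast genes fell. Ednrb went from 39.3 ± 1.7 to 12.2 ± 1.15 FPKM and Tmem100 from 353 ± 16.4 to 176 ± 3.39 FPKM. Kdr, the VEGF receptor gene, fell from 76.2 ± 7.55 to 39.4 ± 8.53 FPKM and Ramp2 from 628 ± 35.5 to 330.3 ± 22.4 FPKM. Of 22 endothelial genes 0 rose, 10 fell and 12 did not pass (0 higher and 14 lower adjusted over the list alone). The endothelial list was lower (camera adjusted p = 1.15e-06, adjusted p = 0.349 with an estimated correlation). Of 14 resident fibroblast genes 0 rose, 7 fell and 7 did not pass (0 higher and 9 lower adjusted over the list alone). Besides Inmt, Itga8 fell from 51.6 ± 0.00707 to 17 ± 5.03 FPKM, Scube2 from 15.8 ± 1.32 to 5.15 ± 1.91 FPKM and G0s2 from 50.6 ± 2.52 to 16.8 ± 8.8 FPKM. The resident fibroblast list was lower (camera adjusted p = 9.27e-05, adjusted p = 0.58 with an estimated correlation). Pericyte and smooth muscle genes did not pass as a list (camera adjusted p = 0.885), with Actg2 (1.39 ± 0.29) and Pdgfrb (0.48 ± 0.09) higher and Trpc6 (-0.45 ± 0.10) lower among 15 (2 higher and 1 lower adjusted over the list alone). Ccl21a rose (0.59 ± 0.13) among 5 lymphatic endothelial genes (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.185), where Lyve1 and Flt4 had log2 changes of -0.37 ± 0.65 and 0.03 ± 0.18.

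Most recruited macrophage genes and some chemokine genes rose. Trem2, a lipid receptor of macrophages, went from 3.9 ± 0.813 to 39.9 ± 9.86 FPKM and Gpnmb from 5.55 ± 0.212 to 37.7 ± 20.6 FPKM. The complement genes C1qb and C1qc rose from 46.1 ± 6.24 to 181 ± 69.9 FPKM and from 37.7 ± 0.233 to 143 ± 43.6 FPKM. Of 16 genes of recruited monocytes and macrophages 11 rose, 0 fell and 5 did not pass (12 higher and 0 lower adjusted over the list alone). The recruited monocyte and macrophage list was higher (camera adjusted p = 1.64e-06, adjusted p = 0.58 with an estimated correlation). Retnla, a marker of alternative activation, rose from 74.9 ± 4.42 to 852 ± 184 FPKM. Il4ra (1.23 ± 0.12) and Clec10a (0.83 ± 0.11) rose beside Arg1. Of 11 genes 5 rose, 0 fell and 6 did not pass (5 higher and 0 lower adjusted over the list alone). The alternative macrophage activation list was higher (camera adjusted p = 0.000687, adjusted p = 0.442 with an estimated correlation). Among chemokines Ccl9 (2.36 ± 0.53), Ccl2 (2.23 ± 0.18), Ccl8 (2.21 ± 0.21) and Ccl12 (1.61 ± 0.24) rose. Of 25 genes 9 rose, 0 fell and 16 did not pass (9 higher and 0 lower adjusted over the list alone). The chemokines and cytokines list was higher (camera adjusted p = 9.27e-05, adjusted p = 0.58 with an estimated correlation). In the list of alveolar macrophage markers, Fabp1, a gene that liver also expresses, went from 19.3 ± 1.99 to 1.5 ± 1.77 FPKM. Ear1 (-1.72 ± 0.08) and Krt79 (-1.66 ± 0.16) fell and Siglec1 rose (0.93 ± 0.19). Of 12 genes 2 rose, 3 fell and 7 did not pass (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.743). Neutrophil genes were lower (camera adjusted p = 0.00488, adjusted p = 0.58 with an estimated correlation). S100a9 fell from 211 ± 37.4 to 71.3 ± 18.8 FPKM and S100a8 from 185 ± 41.7 to 70.4 ± 2.74 FPKM. Retnlg fell from 27.8 ± 7.88 to 9.77 ± 2.8 FPKM and Mpo from 1.89 ± 0.0636 to 0.215 ± 0.276 FPKM. Of 13 genes 0 rose, 5 fell and 8 did not pass (1 higher and 9 lower adjusted over the list alone).

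Lymphoid, antigen presentation and interferon lists did not pass. Foxp3 (0.96 ± 0.17) and Ctla4 (1.04 ± 0.23), genes of regulatory T cells, rose among 13 T cell genes (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.94). Sdc1 rose from 57.1 ± 4.74 to 117 ± 19.8 FPKM among 10 B and plasma cell genes (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.796). Cd79a was at 13.2 and 12.9 FPKM with PBS and 16.4 and 2.34 FPKM with bleomycin. Jchain was at 6.33 and 6.01 FPKM with PBS and 49.3 and 7.82 FPKM with bleomycin. Batf3 rose from 2.53 ± 0.438 to 9.23 ± 3.58 FPKM among 8 dendritic cell genes (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.711), with Clec9a and Ccr7 at log2 changes of -0.90 ± 0.29 and 0.08 ± 0.55. None of 5 NK and cytotoxic genes passed (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0568). Gzma was at 26.9 and 17.2 FPKM with PBS and 7.63 and 0.64 FPKM with bleomycin. Nkg7 was at 10.4 and 8.39 FPKM with PBS and 6.93 and 1.53 FPKM with bleomycin. None of 23 interferon response genes passed (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.621). Ifit3 was at 64.9 and 74.2 FPKM with PBS and 75 and 37.6 FPKM with bleomycin. Gbp2 was at 36.3 and 38.8 FPKM with PBS and 37.4 and 13.8 FPKM with bleomycin. None of 10 MHC class II genes passed (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.94). Cd74 was at 831 and 843 FPKM with PBS and 1915 and 873 FPKM with bleomycin. H2-Aa was at 398 and 397 FPKM with PBS and 751 and 277 FPKM with bleomycin. Complement genes moved in both directions, with C3ar1 (1.45 ± 0.25), Cfb (0.92 ± 0.15) and C5ar1 (0.91 ± 0.10) higher. Of 12 genes 3 rose, 2 fell and 7 did not pass (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.94).

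Red cell and platelet lists were lower, while lists of tissues next to the lung did not pass. Haemoglobin genes fell, Hbb-bs from 1965 ± 426 to 607 ± 173 FPKM and Hba-a1 from 2389.6 ± 418 to 809 ± 174 FPKM. Hba-a2 and Hbb-bt had log2 changes of -1.83 ± 0.28 and -1.73 ± 0.27. Of 5 erythroid genes 0 rose, 5 fell and 0 did not pass (0 higher and 5 lower adjusted over the list alone). The erythroid list was lower (camera adjusted p = 0.00077, adjusted p = 0.58 with an estimated correlation). Platelet genes were lower (camera adjusted p = 0.00272, adjusted p = 0.58 with an estimated correlation). Ppbp fell from 52.4 ± 23 to 7.54 ± 6.58 FPKM and Gp9 from 11.8 ± 3.96 to 0.98 ± 0.594 FPKM. Itga2b fell from 14 ± 5.41 to 4.36 ± 0.643 FPKM and Gp5 from 3.42 ± 0.813 to 0.785 ± 0.375 FPKM. Of 6 genes 0 rose, 4 fell and 2 did not pass (0 higher and 5 lower adjusted over the list alone). Cidec (-1.31 ± 0.12) and Adrb3 (-1.26 ± 0.16) fell among 4 adipocyte genes (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0937). Tnnc1 fell (-0.92 ± 0.16) among 6 cardiomyocyte genes (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.126), with Actc1 and Tnnt2 at -0.48 ± 0.37 and 0.09 ± 0.40. Of 6 mesothelial genes none passed (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.244). Msln was at 84.5 and 57 FPKM with PBS and 60.9 and 257 FPKM with bleomycin and Upk1b at a log2 change of -0.36 ± 0.23. Of 3 skeletal muscle genes none passed (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.86), with Tnnt3 and Tnni2 at 0.20 ± 0.12 and -0.55 ± 0.20. Cd1d1, the 1 thymocyte gene tested, was at 7.69 ± 0.594 FPKM with PBS and 6.79 ± 0.226 FPKM with bleomycin, with 0 higher and 0 lower adjusted over the list alone, and 0 genes of mast cells, basophils and eosinophils reached the filter.

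Clock genes differed in both directions. Hlf fell from 18.3 ± 1.4 to 4.52 ± 1.8 FPKM, Tef from 172 ± 3.75 to 58.3 ± 12.5 FPKM and Per3 from 24 ± 2.74 to 8.85 ± 3.12 FPKM. Nfil3, a repressor of the same output genes, rose from 3.18 ± 0.184 to 10.3 ± 2.02 FPKM. Of 15 clock genes 1 rose, 5 fell and 9 did not pass (2 higher and 10 lower adjusted over the list alone). The circadian clock list was lower (camera adjusted p = 0.00773, adjusted p = 0.58 with an estimated correlation). Immediate early genes did not pass (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.103). Dusp1 was at 115 ± 16.9 FPKM with PBS and 122 ± 22.2 FPKM with bleomycin. Ier3 was at 94.2 ± 0.134 FPKM with PBS and 140.4 ± 33.4 FPKM with bleomycin. In the unfolded protein and heat shock list Sdf2l1 rose from 14.3 ± 0.636 to 31.5 ± 0.283 FPKM and Herpud1 (-0.68 ± 0.08), Atf5 (-0.64 ± 0.10) and Ddit3 (-0.58 ± 0.09) fell. Of 20 genes 3 rose, 3 fell and 14 did not pass (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.796).

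Of 53 lists tested by camera with a preset correlation, 16 were higher, 9 lower and 28 did not pass. By camera with an estimated correlation 0 passed, the lowest adjusted p being 0.349, with 6 at an unadjusted p under 0.05. That form rests on 2 residual degrees of freedom for every list and could hardly call one here. The degrees of freedom alone do not account for the loss, which differed between lists of like preset p. By camera, the unadjusted p went from 1.3e-07 to 0.0284 for endothelial genes and from 2.17e-07 to 0.285 for recruited macrophage genes. For lists of the latter kind, p-values with the preset correlation may be too small. With fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, 13 lists passed, 10 higher and 3 lower. The higher ones were the transitional epithelium, p53, myofibroblast, alternative activation, cell cycle, matrix remodelling, interstitial matrix, nucleotide, glutamine and hexosamine lists. The lower ones were the endothelial, xenobiotic and glycerolipid lists. The bleomycin libraries differed by medians of 0.57, -0.86 and -0.68 over cholesterol synthesis, ciliated cell and chemokine genes, more than the median changes of 0.40, -0.84 and 0.59 between the groups. In 11 lists, none of them called by camera, the median, the mean, the camera direction and the fry direction were not all of 1 sign. The median was above 0 and the mean below it for fatty acid oxidation, alveolar macrophage, MHC class II, alveolar type I and unfolded protein genes, with camera down for the alveolar macrophage and type I lists and up for the others. The median was below 0 and the mean above it for glutathione, complement and pericyte genes, with camera up. Median and mean were below 0 and camera up for T cell genes. Fry ran against camera for fatty acid synthesis, tryptophan and NAD, and glutathione genes. The lowest fry adjusted p values were 0.00136 for transitional alveolar epithelium and 0.00757 for the p53 response and for endothelial genes.

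**Figure D3:**
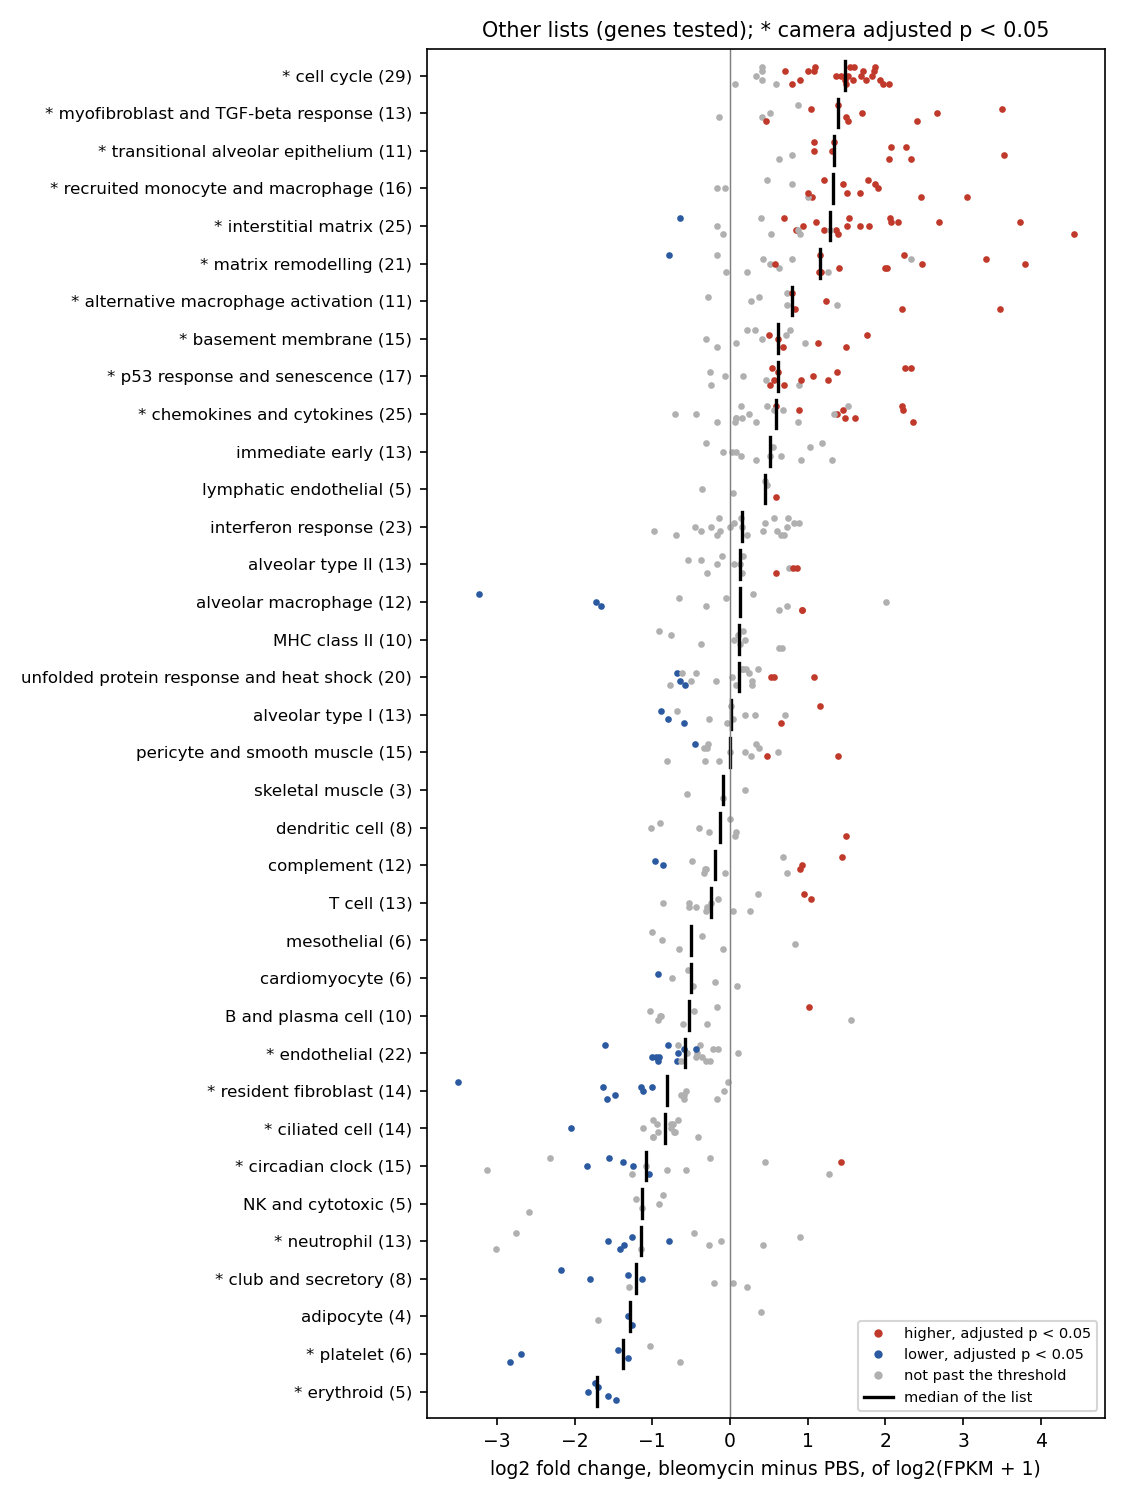
Log2 fold change (bleomycin minus PBS, on log2(FPKM + 1)) of each tested gene of the matrix, cell type and response lists with at least 3 tested genes, one point per gene, coloured by its limma call, with the list median as a black bar. The cell cycle has the highest median, 1.48, and erythroid genes the lowest, -1.71.

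Signals that belong to no fixed list also followed the groups. Apart from Alb and Mup10, which are among the 10 largest falls, the single genes named here were chosen after their values were seen. The Y-linked gene Eif2s3y stood at 26.4 and 28.9 FPKM with PBS and Kdm5d at 4.38 and 4.29 FPKM, and both were listed at 0 in both bleomycin libraries. Ddx3y stood at 17.6 and 15.2 FPKM with PBS and 0.01 and 0.02 FPKM with bleomycin. Uty stood at 3.57 and 3.28 FPKM with PBS and 0.01 and 0.01 FPKM with bleomycin. The genes Eif2s3x (0.76 ± 0.11), Kdm5c (0.66 ± 0.11) and Ddx3x (0.44 ± 0.08), which escape X inactivation, rose, and Kdm6a was at 6.32 ± 0.127 FPKM with PBS and 8.88 ± 0.601 FPKM with bleomycin (adjusted p = 0.0504 by limma). The labels used here give no sex, so every gene group above was compared between libraries that also differ in these sex-linked transcripts. The albumin gene Alb stood at 14.4 and 14.2 FPKM with PBS and 1.01 and 0.66 FPKM with bleomycin. Apoa2 stood at 25.7 and 26 FPKM with PBS and 2.47 and 3 FPKM with bleomycin and Mup10 at 14.9 and 15.7 FPKM with PBS and 1.04 and 1.01 FPKM with bleomycin. Of further hepatocyte genes, 41 of 44 at 0.1 FPKM or more with PBS were lower in both bleomycin libraries than in both PBS libraries. Many of these lay below the 1 FPKM filter, and a minimum set on the PBS level favours a fall. Hepatocyte, haemoglobin and platelet transcripts were lower in the same libraries as the xenobiotic, neutrophil, club cell and endothelial lists. With 2 groups that holds for any fallen list. PBS 2 minus PBS 1 had log2 medians of 0.76, 0.34 and 0.27 over platelet, erythroid and neutrophil genes. Over club cell, xenobiotic and endothelial genes they were -0.34, -0.18 and -0.01. In the same orders bleomycin 2 minus bleomycin 1 had medians of -0.34, -0.59 and -0.44, and of -0.40, -0.21 and -0.004. A shared source was not tested. Without genes of the X and Y chromosomes 1072 genes rose and 955 fell, and without hepatocyte, haemoglobin, platelet and clock genes 1111 rose and 954 fell, both alternatives having been added after seeing the data. These fits kept 12588 and 12928 of the 12986 genes. They take out the marker genes only, so they cannot show whether the other genes are free of such effects.

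**Figure D4:**
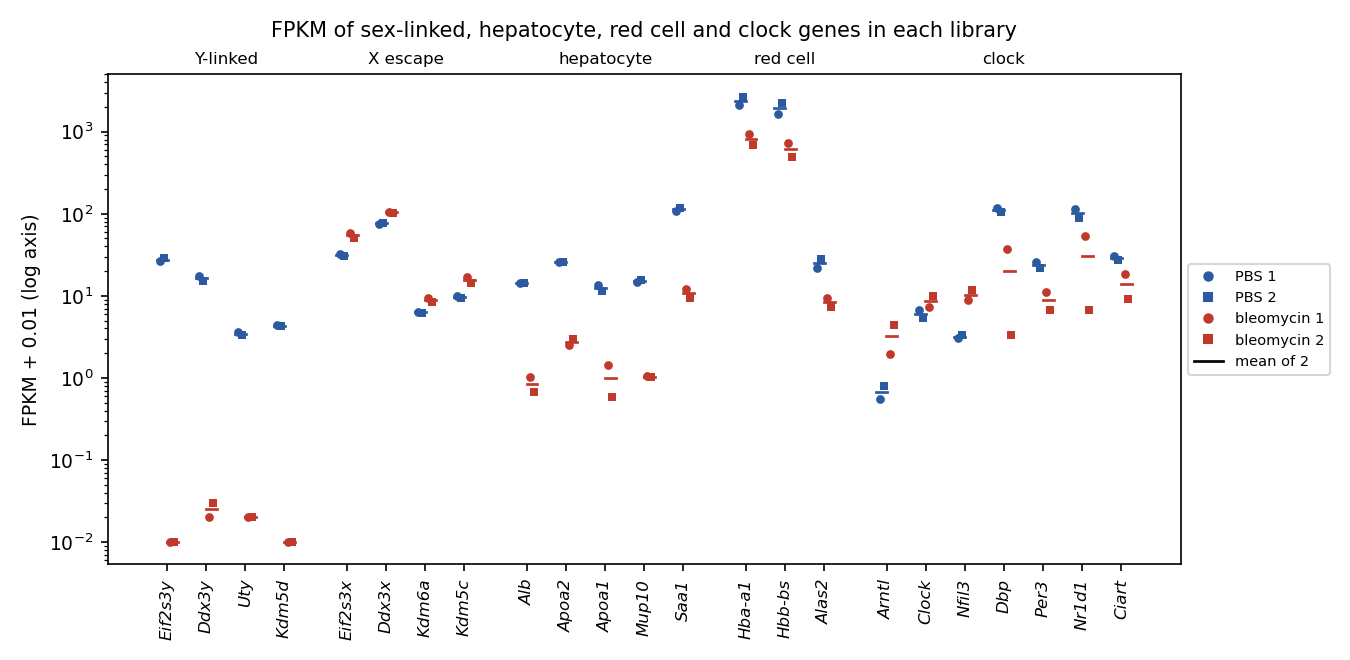
FPKM (with 0.01 added, log axis) of Y-linked genes, genes escaping X inactivation, hepatocyte, red cell and clock genes in the 2 PBS and 2 bleomycin libraries, each symbol a library and each bar the mean of 2. Y-linked genes lie at or below 0.02 FPKM in both bleomycin libraries, and Dbp lies at 37.2 and 3.33 FPKM there.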

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

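The settings that leave out genes of the X and Y chromosomes or hepatocyte, blood and clock genes, and the array weights by group, were chosen after seeing the data. The 1116 rises and 998 falls, the 42 and 30 metabolic ones and the lists called by camera stayed within 1.5 times under other pseudocounts, filters, scalings and eBayes settings, with 811 to 1444 genes higher and 739 to 1174 lower. Rescaling to TPM gave 1444 higher and 887 lower, 61.9% of calls higher against 52.8%. With array weights by group 1226 genes rose and 1155 fell. Deviations from the group means of libraries of the same replicate number had a correlation of 0.023. With 2 libraries per group this is a single comparison and cannot exclude pairing, which the labels do not state. With the replicate block 842 genes rose and 799 fell. Leaving out 1 library each gave 0 to 2393 genes higher and 0 to 3180 lower, 0 to 102 metabolic genes higher and 0 to 67 lower, and 16 to 21 lists higher and 10 to 14 lower. With 1 PBS library left, limma takes its spread from the bleomycin pair, and the other way round, so the lone library is assumed to vary like the other group. With an estimated correlation camera called 0 lists higher and 0 lower, with 6 at an unadjusted p under 0.05, and fry called 10 higher and 3 lower. The estimated form rests on 2 residual degrees of freedom for every list and has little power here. Its result therefore does not decide the matter. For the endothelial and recruited macrophage lists, alike by the preset form, the loss differed, so the degrees of freedom alone do not explain it. Of 200 named genes 163 were called, and 0 of these changed direction under the planned settings that tested them. Calls were lost for 162 without either PBS library, 45 without the filter, 15 with the replicate block, 11 without the trend and 1 to 5 under other pseudocounts, scalings, robust eBayes and the 5 FPKM filter, where some named genes were not tested. Some genes that were not called changed sign. Rescaled to TPM, log2 changes were 0.033 for Ager and 0.0015 for Pparg. Leaving out 1 library each, log2 changes ranged from -0.33 to 0.26 for Ager, -0.15 to 0.038 for Pparg, -0.11 to 0.26 for Dusp1, -0.41 to 0.60 for Tnnt2 and -0.76 to 0.91 for Ccr7. The log2 fold change of Lyve1 ranged from -1.33 to 0.60 and the log2 fold change of Cd79a from -2.08 to 0.30. The ranges were -0.52 to 0.92 for H2-Aa, -0.87 to 0.11 for Ifit3 and -0.21 to 0.27 for Flt4. For Msln, Actc1 and Cpt1a the ranges were -0.19 to 1.87, -1.03 to 0.069 and -0.37 to 0.16. The depth, 17000000 to 17500000 fragments, limits genes with a mean below 1 FPKM, which were left out of the main fit and tested in the setting without the filter.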

Other observations

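The tests on genes escaping X inactivation and on clock genes were chosen after the values were seen; those on detection and on hepatocyte genes not looked at before were fixed before their values were seen. Among lists with at least 3 tested genes, the bleomycin libraries differed most in immune ones. On the log2 scale bleomycin 2 minus bleomycin 1 had medians of -1.57 over B and plasma cell genes, -1.49 over interferon response genes, -1.45 over NK and cytotoxic genes and -1.23 over MHC class II genes, while PBS 2 minus PBS 1 had medians of -0.02, 0.15, -0.28 and 0.03. Cholesterol synthesis and mesothelial genes went the other way, with medians of 0.57 and 0.63 between the bleomycin libraries and 0.13 and -0.47 between the PBS libraries.

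Y-linked transcripts were near 0 in both bleomycin libraries, and their PBS levels were between 3.42 and 27.6 FPKM. Poorer detection at that level is argued against, since 1 of 7321 autosomal genes of the same PBS level, 0.0137%, was 20 times lower in both bleomycin libraries. Male mice in the PBS group and female mice in the bleomycin group may account for it, as the 4 genes escaping X inactivation had a median log2 change of 0.55 and were higher in both bleomycin libraries. Genes of X and Y made up 3.26% of the called genes and 3.06% of the tested ones. Effects of sex on autosomal genes cannot be parted from those of bleomycin in this design, and this stays open for every gene group.

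Hepatocyte transcripts were lower after bleomycin, with a median log2 ratio of mean FPKM, nothing added, of -3.83 (SD 0.48) over 14 genes seen among the falls. A change of acute-phase genes alone is argued against, because 44 hepatocyte genes not looked at before had a median log2 ratio of -2.55 (SD 1.47), with 0.01 added to both means. Liver RNA in the PBS libraries may be the source, since 93.2% of these 44 genes were lower in both bleomycin libraries than in both PBS libraries, the others being F9, Lcat and Urah. Many of the 44 lay below the 1 FPKM filter, and Serpina1a, Serpina1d and Serpina1e belong to a family with members seen before. The share for other genes of that level was not taken. The minimum of 0.1 FPKM was set on the PBS mean, which favours a fall. It left out Cyp2d9, at 0.07 and 0.11 FPKM with PBS and 0.03 and 0.21 FPKM with bleomycin. Of all tested genes 66.5% separated the groups in either direction. The most abundant of the 14 were the acute-phase genes Saa1 and Saa2, at 108.6 and 119 FPKM and at 107 and 114 FPKM with PBS. They lay above Hpx, at 42.5 and 46.7 FPKM, and Alb, at 14.4 and 14.2 FPKM. Whether this order is that of liver was not tested. The PBS libraries differed by a median log2 of 0.01 over the 14 genes. Lung cells also express some of these genes, and a fall in blood-borne or lung-made transcripts after bleomycin was not tested.

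Clock genes parted after bleomycin, with a median log2 change of 0.86 over Arntl, Npas2, Clock and Nfil3 and of -1.26 over 11 others, groups formed after the values were seen and leaving out Cry1. Nfil3 was the 1 called gene of the first 4. A different time of day at collection may account for the pattern, as over these 15 genes the difference between the bleomycin libraries correlated with the change of bleomycin 1 from PBS at 0.66 (0.65 over all 16 genes of the fixed list), although both hold bleomycin 1 with opposite signs, and 10000 random lists matched on mean FPKM had a median of -0.118, with 2.32% at or above it. The test and the random lists, which hold any effect of bleomycin, were chosen after that value and the 0.87 with the group difference, which holds bleomycin 2 on both sides, were seen. Genes are not independent replicates, no collection time is in the labels used here, and time and treatment cannot be told apart.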
